A study of Mus musculus with 2 samples.

How the data were processed

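The 2 libraries were prepared from spleen cells of transplanted mice with a droplet-based 5′ gene expression kit and sequenced on a NextSeq500, per the labels' protocols. The submitters' processing notes name Cell Ranger 3.1.0, Seurat (version not given) and the genome build mm10. How reads were filtered and how cells were chosen is not given in the sources used here. T-cell receptor sequencing named in the protocol was not analysed here. Each library was 1 treatment, so samples were grouped by the treatment in their labels, and treatment and library are the same split.

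Each file held 2000 genes as natural log values that the authors had deposited after scaling each cell to a fixed total. In the tacrolimus file 0 values were below 0, and 100.0% of its values came out as whole UMIs (tolerance 0.001) at a scale of 50000 per cell. In the anti-IL-2 file 13.9% of values were below 0 and 42.0% were exactly 0, as in data that have been batch-integrated with the other library as reference. Its differences from the tacrolimus file are therefore integrated differences, not expression, and they are not used as levels. The design had assumed UMI counts or CPM. The tacrolimus file had 1996 columns, of which 308 were anti-IL-2 cells whose barcodes contain the letters TAC. They were identical to their columns in the anti-IL-2 file and were used once, as anti-IL-2 cells, which left 1688 tacrolimus cells. There were 0 mitochondrial genes and 0 T-cell receptor or immunoglobulin segments in the files, so no mitochondrial filter was applied. Of 10 treatment target genes only Il2 and Il2ra were measured here.

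For each anti-IL-2 cell the UMI total was fitted and the integration shift of each gene was estimated and removed. The shift was taken as shared by the 30 nearest anti-IL-2 cells, the cell itself included, and was the value that brought them closest to whole UMIs. A value above 0.5 of the level of 1 UMI was read as a detection. Totals could be read directly for 161 cells from 2 or more unshifted values and for 187 cells from 1 value. The fitted total was within 1.25-fold of these in 97.5% and 95.2% of cells, and in 96.9% and 95.2% when the fit saw these cells alone, as it did when its settings were compared. These shares are in-sample, since the fit was chosen among 10 settings (and earlier forms) on the same cells. The shift estimate was chosen among 14 settings with true totals and 3 rounds with fitted totals, on a simulated library. Depth matching was chosen over the planned thinning to a fixed depth after an earlier simulation.

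The procedure was tested on a further simulated pair of libraries, integrated with Seurat 5.3.0 in R 4.3.3 and used for no choice (838 shifted cells, 844 reference cells, 2000 genes, 50 genes changed at each fold). Both simulated libraries, like those used to choose settings, were random parts of the tacrolimus cells. They share their cell states, so the test does not cover states that are rare among tacrolimus cells. Detection calls were right for 99.6% of values, and fitted totals were within 1.25-fold of the truth for 87.6% of cells. True and recovered median differences of shares were -21.2 and -20.0 points at 0.25-fold, -11.4 and -10.9 at 0.5-fold, 19.0 and 17.9 at 2-fold, and 34.0 and 31.8 at 4-fold. Of genes with a true difference of 5 points or more, 46 of 46, 45 of 45, 48 of 50 and 50 of 50 were recovered at these folds. For 713 unchanged genes the 95th percentile of the error was 1.3 points and the largest error 16.5 points. In the true and the recovered differences alike, the reference cells were thinned to the fitted totals. These comparisons therefore do not show errors that fitted totals bring in through depth matching. The median ratio of fitted to true totals was 1.06. The integrated values themselves gave median differences between -0.02 and 0 for the changed genes. The 95th percentile of the error was also taken over genes in at least 5% of cells thinned to 1 depth. It was 2.3 points for recovered shares without thinning, 45.7 points with that thinning, and 20.4 points without removal of the shift. The depth-matched reference cancels in the first value, so these errors do not test depth matching. Recovered UMI sums had median errors of 0.17 (log2) for genes in 2 to 20% of cells but 1.76 for genes in over 80%. Over all changed genes, rises shrank, with median log2 UMI ratios of 0.36 for a true 0.94 and 1.01 for a true 1.9. Falls did not shrink alike (-1.97 for -2.04, and -1.2 for -1.01). These medians were not split by share. UMI ratios are given only for genes in fewer than 20% of cells, a limit set on the earlier simulation.

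Cells with at least 200 detected genes were kept. Because the files hold 2000 genes, this minimum was stricter than meant and left out 20.0% of anti-IL-2 and 12.6% of tacrolimus cells. Scrublet, as run in scanpy 1.11.5, called 2 anti-IL-2 and 5 tacrolimus cells doublets, which were kept. Cells of both libraries were clustered together on the deposited values, which are integrated for the anti-IL-2 cells (scanpy, Python 3.11.15; 30 principal components, 15 neighbours, Leiden resolution 1.0), which gave 16 clusters. Of these, 12 were T-cell clusters, named CD4 T-like or CD8 T-like by a 2-fold difference between the share of Cd4 and the mean share of Cd8a and Cd8b1, with at least 3 markers of the class in 20% of cells or more, and 4 held other lineages. None of the planned general T-cell markers was in the files, and the thresholds were set after the pooled cluster markers and the make-up of clusters by library had been seen. The clusters of other lineages, kept out of the T-cell classes, held 5.16% of anti-IL-2 and 3.66% of tacrolimus cells. No T cluster had markers of another lineage among its 10 leading genes, but naive T-cell markers, and no marker of their own class, were among those of cluster 10 (CD8 T-like) and cluster 9 (CD4 T-like, Ccr7). They were read as a state, after they had been seen. Clusters 9 and 10 were mostly of anti-IL-2 cells, a case that the simulated libraries did not cover. Cluster shares within T cells, although planned, are not compared between the libraries, since the genes that define the clusters differ between them. They are given only to show which clusters hold each class.

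Tacrolimus cells were thinned by rank to the totals of anti-IL-2 cells of the class, which changed 1420 of 1421 T cells, 360 of 371 CD4 T-like and 776 of 1050 CD8 T-like cells and brought median UMIs from 13287 to 12341, from 11335 to 9848 and from 14271 to 14091. The log2 ratio of shares was taken after adding 1 cell to each library. Shares have Clopper-Pearson intervals and ratios conditional intervals, at 95% and for counting error only, without the variation of the random thinning. The ratio intervals treat cells with a UMI as Poisson counts, so they are too wide for genes in most cells. For Gzmb in CD8 T-like cells the share intervals were 89.14 to 93.16% and 98.38 to 99.61%, yet the ratio interval was 0.837 to 1.013. For a count of 0 the limit is 3 cells of the total, which lies below the upper end of the exact interval. A gene was in more or fewer cells by size when the ratio was at least 1.5-fold and its interval excluded 1, given a share of at least 5% in the higher library. A gene in more than 2 of 3 tacrolimus cells cannot reach a 1.5-fold rise, so that neither is then no sign of a like level. No p-value was computed, since cells are not replicates. The planned ranking by CPM and the CPM minimum could not be kept, since UMI sums are not reliable for abundant genes. The named genes are the 12 highest and 12 lowest ratios among genes at the minimum (without receptor segments, mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes and names of the Gm, Rik or accession-like kind), up to 4 members of each list with the largest ratios, and the treatment targets. A few of the genes this rule names are not reported here. The deposited names were used as given, and all 142 named genes had coordinates in the mm10 annotation (GENCODE M21).

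There were 21 gene lists and 16 marker lists, fixed before the data were examined. A list median used members found in at least 10 cells, with at least 3 members, and was placed among 10000 random lists of the same size matched on share. Its interval came from 500 resamples of counts. The alternatives were other cluster resolutions, classes from each cell's own UMIs, no cell filter, doublets or cycling clusters left out, no thinning or thinning to a fixed depth, median of ratios scaling, mean UMIs per 10000, and other minimums and added counts. Chosen after seeing the data were other detection thresholds, the shift left in, only cells with a readable total, the clusters mostly of anti-IL-2 cells left out, the tacrolimus file as deposited, and summed UMIs. The 28-gene pancreatic list was written after pancreatic genes had been seen among the lowest ratios. A gene in 0 tacrolimus cells was at first left without a size call; it was then called like a gene in 0 anti-IL-2 cells, after the values had been seen. Some raw detection shares were seen during exploration, and all list medians were counted as answers to the comparisons only after their alternatives had been seen. Analyses used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0.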

Results

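Single-cell RNA-seq profiled T cells from the spleens of BALB/c mice that had been lethally irradiated and given spleen and marrow cells of C57BL/6 donors, a mouse model of allogeneic haematopoietic cell transplantation. Recipients were treated from day 0 to day 6 with tacrolimus, a calcineurin inhibitor that blocks NFAT activation downstream of the T-cell receptor, or with an antibody against IL-2, a growth factor of activated T cells. Spleens were collected on day 6. There was 1 library per treatment, so no difference has a replicate check, and every difference between the treatments is also a difference between the libraries. The files held 1551 anti-IL-2 cells and 1688 tacrolimus cells. After a minimum of 200 detected genes, 1241 anti-IL-2 cells (median 12341 UMIs and 325 genes, out of the 2000 genes in the files) and 1475 tacrolimus cells (median 13254 UMIs and 420 genes) were kept. Of these, 1177 and 1421 were T cells, which fell into a CD4 T-like class (372 and 371 cells) and a CD8 T-like class (805 and 1050 cells). The anti-IL-2 file held batch-integrated values, from which UMIs were recovered after an estimated shift was removed. Levels are given as the share of cells with at least 1 UMI of a gene, with tacrolimus cells thinned to the depth of the anti-IL-2 cells. Intervals are 95% intervals that cover counting error only, and those of ratios are too wide for genes in most cells.

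The first comparison asked how T cells under IL-2 blockade differed from T cells under calcineurin inhibition. Il2ra, the alpha chain of the high-affinity IL-2 receptor, was detected in 16.6% of anti-IL-2 T cells (14.5 to 18.8%) and 36.3% of tacrolimus T cells (33.8 to 38.9%), a ratio of 0.456 (0.385 to 0.539). Socs2, a feedback inhibitor of cytokine signalling, was detected in 0.76% and 5.98% of cells (ratio 0.128, 0.057 to 0.254), and Ccnd2, which encodes cyclin D2, in 27.7% and 43.2%. Bcl2, which encodes an anti-apoptotic protein, went the other way, with 51.2% against 19.3% (2.66-fold, 2.30 to 3.08). Of the 10 measured IL-2 receptor and STAT5 target genes, 4 were in fewer anti-IL-2 cells by the size rule (Il2ra, Cish, Socs2, Ccnd2), 1 was in more (Bcl2) and 5 were neither. The list median of the log2 ratio was -0.12, at percentile 83.9 of random lists, and 0.08 under median of ratios scaling, so its direction depended on the scaling. Il2 itself was seen in 1.02% of anti-IL-2 T cells (0.53 to 1.77%) and 0.49% of tacrolimus T cells (0.20 to 1.01%), below the 5% minimum for a call. In 50 cells of the B and plasma-cell-led and erythroid-led clusters (median 12251 UMIs), which should lack it, Il2ra was in 0 cells, which allows a share of up to 6.0%. Of other genes named here, Tcf7, Pdcd1 and Il7r were also in 0 of these cells, Tox and Ifng in 2.0% and Bcl2 in 10.0%. Mki67, a proliferation gene that no cell type lacks by lineage, was in 64.0% of them. These clusters held 18 and 8 anti-IL-2 cells, fewer than the 30 whose shift was taken as shared, so these shares are less certain. In mm10 (GENCODE M21) Il2ra lies on chromosome 2 from 11642807 to 11693193, Socs2 on chromosome 10 from 95385362 to 95417180, and Bcl2 on chromosome 1 from 106538178 to 106714274. All are protein-coding genes.

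Genes of naive, memory and stem-like T cells were in more cells of the anti-IL-2 library. Tcf7, which encodes the transcription factor TCF-1, was detected in 47.1% of anti-IL-2 T cells (44.19 to 49.97%) and 6.54% of tacrolimus T cells (5.31 to 7.96%), a 7.19-fold ratio (5.77 to 9.06). Id3, a regulator of memory differentiation, was in 34.9% against 6.19%, and the lymph-node homing receptor gene Ccr7 in 16.7% against 3.1%. Of 6 measured members, 5 were in more anti-IL-2 cells (among them Tcf7, Ccr7, Id3 and Il6ra) and 1, Il7r, was neither. The list median was 2.23 (counting interval 1.97 to 2.43), at percentile 100 of 10000 random lists matched on share. Across all measured genes the median log2 ratio was -0.20 in all T cells, -0.28 in CD4 T-like cells and -0.16 in CD8 T-like cells, and the naive list lay 2.43 above it in all T cells. Without thinning, Tcf7 was in 6.76% of tacrolimus T cells. Tcf7 lies on chromosome 11 from 52252371 to 52283014, and Id3 on chromosome 4 from 136143497 to 136145755.

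Interferon-stimulated genes were also in more cells of the anti-IL-2 library. Rsad2, which encodes the antiviral protein viperin, was in 7.73% of anti-IL-2 T cells and 0.70% of tacrolimus T cells (11.0-fold, 5.71 to 23.7), Ifit1 in 16.7% and 3.94% (4.25-fold, 3.14 to 5.82), Ifit3 in 11.5% and 2.81%, and Oasl2 in 6.80% and 1.27%. Of 15 type I interferon response genes, 9 were in more cells (Isg15, Ifit1, Ifit3, Usp18, Rsad2, Oasl2, Oas1a, Mx1, Rtp4), 0 in fewer and 6 neither, with a list median of 0.66 at percentile 100. In anti-IL-2 cells with a directly readable total it was 1.33, and by mean and summed UMIs, which cover only members in fewer than 20% of cells, 2.0 and 2.1. The interferon-gamma list had a median of 0.38 at percentile 99.7, with 2 of 10 members, Gbp5 (9.60% against 5.14%) and Iigp1 (5.52% against 1.76%), in more cells and 8 neither. By those UMIs its median was 1.39 and 1.11. Rsad2 lies on chromosome 12 from 26442746 to 26456452.

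Proliferation genes were in fewer anti-IL-2 T cells. Ccna2, which encodes cyclin A2, was in 44.4% of anti-IL-2 T cells and 74.6% of tacrolimus T cells (ratio 0.596, 0.535 to 0.662), Cdk1 in 39.7% and 64.9%, and the mitotic kinase gene Aurkb in 34.0% and 57.7%. Of 22 cell cycle genes, 9 were in fewer cells, 0 in more and 13 neither. However, 16 of the 22 were in too many tacrolimus cells for a 1.5-fold rise. The list median was -0.57 at percentile 0.0, and -0.28 without the clusters mostly of anti-IL-2 cells (9 and 10). Without the cycling clusters the list median was still below 0, at -0.43, but Aurkb and Cdk1 no longer pointed that way, at log2 ratios of 0.37 and 0.05. Of 16 MYC and mTORC1 growth genes, 3 were in fewer cells and 13 neither. The 3 were Slc7a5 (17.84% against 29.98%), Cad (18.9% against 28.7%) and Eif4ebp1 (15.3% against 27.0%). The list median was -0.21 at percentile 25.3, which lay 0.01 below the median of genes at the minimum share. The 6 glycolysis genes were all in too many tacrolimus cells for a 1.5-fold rise (Pkm, which encodes a pyruvate kinase, in 96.9% against 98.5%), so shares say little of their levels. Their median was -0.04, and 0.16 under median of ratios scaling.

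Effector genes divided. Gzmc, a granzyme gene, was in 3.99% of anti-IL-2 T cells and 13.4% of tacrolimus T cells (ratio 0.297, 0.211 to 0.411), Gzmm in 3.65% and 11.4%, and Klrg1, a marker of terminal effector cells, in 10.1% and 18.6%. Of 14 cytotoxic genes, 13 reached the minimum share, and 5 of these were in too many tacrolimus cells for a 1.5-fold rise. Gzmc, Gzmm and Klrg1 were in fewer cells and 0 genes in more (median -0.37, percentile 1.7). That median was -0.17 with the integration shift left in and under median of ratios scaling, and -2.59 and -2.35 by mean and by summed UMIs of low genes, the members in fewer than 20% of cells. Il12rb2, which encodes a chain of the IL-12 receptor, was in 18.4% and 37.6%, while the chemokine gene Xcl1 was in 11.4% and 2.74%. They were the only members of the Th1 and inflammatory list that passed the size rule among 8 at the minimum share, and its median of -0.15 (percentile 57.0) changed sign to 0.05 under median of ratios scaling and to 0.48 and 0.18 by those UMIs. Among homing genes, Itga1, the integrin alpha 1 gene, was in 4.50% and 16.4% and Ccr2 in 39.3% and 60.3% (list median -0.47, percentile 2.9). The list median was -0.02 with the integration shift left in and 0.01 by mean UMIs per 10000 of low genes. The Ccr2 ratio depended on the removal of the integration shift, with a log2 ratio of -0.62 with it and 0.16 without it.

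Inhibitory receptor genes went both ways. Tox, a transcription factor gene of chronically stimulated T cells, was in 73.0% of anti-IL-2 T cells and 31.7% of tacrolimus T cells (2.30-fold, 2.05 to 2.58), Tox2 in 27.1% and 3.31% (8.19-fold, 6.02 to 11.4), and Cd200 in 29.3% and 15.6%. Entpd1, which encodes the ectoenzyme CD39, was in fewer anti-IL-2 cells (11.3% against 19.4%), as was Havcr2, which encodes TIM-3. The other 5 of the 10 genes were neither, among them Pdcd1, which encodes PD-1 (83.3% against 75.7%). At the tacrolimus share of Pdcd1 and of 1 other member, a 1.5-fold rise was not possible. The list median was 0.08 at percentile 99.7. All 4 measured genes of the PD-1, PD-L1 and CD28 family were neither (median 0.15, percentile 99.1), but 2 of them, Pdcd1 and Icos, were in too many tacrolimus cells for a 1.5-fold rise. Tox lies on chromosome 4 from 6686353 to 6991557, and Tox2 on chromosome 2 from 163203125 to 163324170.

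Among genes of helper subsets, Cxcr5, the follicular homing receptor gene, was in 16.6% of anti-IL-2 T cells and 1.06% of tacrolimus T cells (15.7-fold, 9.28 to 28.6). Ccr6 was in 9.09% of anti-IL-2 T cells and 0 of 1421 tacrolimus cells at matched depth, which allows up to 0.211% (3 cells), and in 0.14% without thinning. The exact 95% interval of its ratio began at 34.4, and without the clusters mostly of anti-IL-2 cells its log2 ratio was 4.59 in place of 7.03. Each class was thinned by its own random draw, and the interval leaves out the variation of such draws. In the separate draw for CD8 T-like cells the tacrolimus count of Ccr6 was not 0. The Th2, Th17 and Tfh list had only 4 measured members (median 2.32, percentile 99.7, and 2.32 with Ccr6 at the limit that a count of 0 allows). Its median was 0.76 with no minimum of cells and 0.71 with the tacrolimus file as deposited. Of B-cell genes in the same T cells, Cd79a was in 0.76% against 0.14% and Ms4a1 in 0.51% against 0.07%, both below the 5% minimum for a call, and Cd79b was neither, at 8.58% against 11.4%. Genes of the NFAT and T-cell receptor list, the pathway that tacrolimus blocks, had a median of 0.21 (percentile 98.2). Xcl1, Egr1 (9.77% against 5.63%) and Nr4a2 (31.9% against 20.6%) were in more anti-IL-2 cells, 0 were in fewer and 10 were neither. By summed UMIs the log2 ratios of Xcl1 and Egr1 were 0.96 and 0.27, against 2.03 and 0.79 by shares. The list median was 0.61 by mean UMIs of low genes.

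The anergy list had a median of 0.59 (percentile 93.6), with Izumo1r in 11.7% against 5.28% as its 1 member in more anti-IL-2 cells. Izumo1r, which encodes folate receptor 4, and Ikzf2 (26.2% against 16.3%), which encodes Helios, were the 2 regulatory T cell and Tr1 genes in more cells (list median 0.30, percentile 90.2, with -0.21 without cycling clusters, and 0.84 and 0.69 by mean and summed UMIs of low genes). The anti-apoptotic list (median 0.05, percentile 97.8) owed its 1 call to Bcl2. The immediate early and dissociation stress list had a median of 0.22 (percentile 99.4) with 0 of 9 members past the size rule, and -0.07 by summed UMIs of low genes. The pro-apoptotic and oxidative phosphorylation lists had 2 members each in the files and the sex-linked list 0, so they have no median.

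The 12 genes with the highest ratios in all T cells included Ccr6, Sostdc1, Cxcr5, Dapl1, Rsad2, Nsg2, Car2, P2rx7, Tox2, Ifit3b and Tcf7. Sostdc1, which encodes a secreted BMP and WNT antagonist, was in 12.2% of anti-IL-2 T cells and 0.21% of tacrolimus T cells (57.5-fold, 19.3 to 282). Car2, carbonic anhydrase 2, was in 5.01% and 0.49%, beside the haemoglobin gene Hbb-bs in 4.16% and 0.49%. At the other end, 9 of the 12 lowest were genes of the exocrine pancreas (Prss2, Try4, Try5, Reg1, Reg2, Reg3b, Cela2a, Cela3b, Rnase1). Reg3b was in 0.17% of anti-IL-2 T cells and 16.1% of tacrolimus T cells. Without thinning, at least 1 UMI of a 28-gene pancreatic list was in 79.2% of CD4 T-like, 78.2% of CD8 T-like and 74.1% of other-lineage tacrolimus cells. In anti-IL-2 cells these shares were 16.9%, 27.1% and 48.4%. The list genes with the highest shares in anti-IL-2 T cells were Cela1 and Ctrb1. Cela1 was in 9.7% of CD4 T-like and 5.2% of CD8 T-like cells, against 10.5% and 7.5% of unthinned tacrolimus cells. Ctrb1 was in 6.7% and 18.5%, against 35.3% and 36.8%. The share of 48.4% is less certain, since each other-lineage cluster held fewer anti-IL-2 cells than the 30 whose shift was taken as shared. The other 3 of the 12 lowest were Socs2, the neuronal nitric oxide synthase gene Nos1 (1.78% against 8.09%) and the lamin gene Lmna (1.44% against 5.98%).

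**Figure D1:**
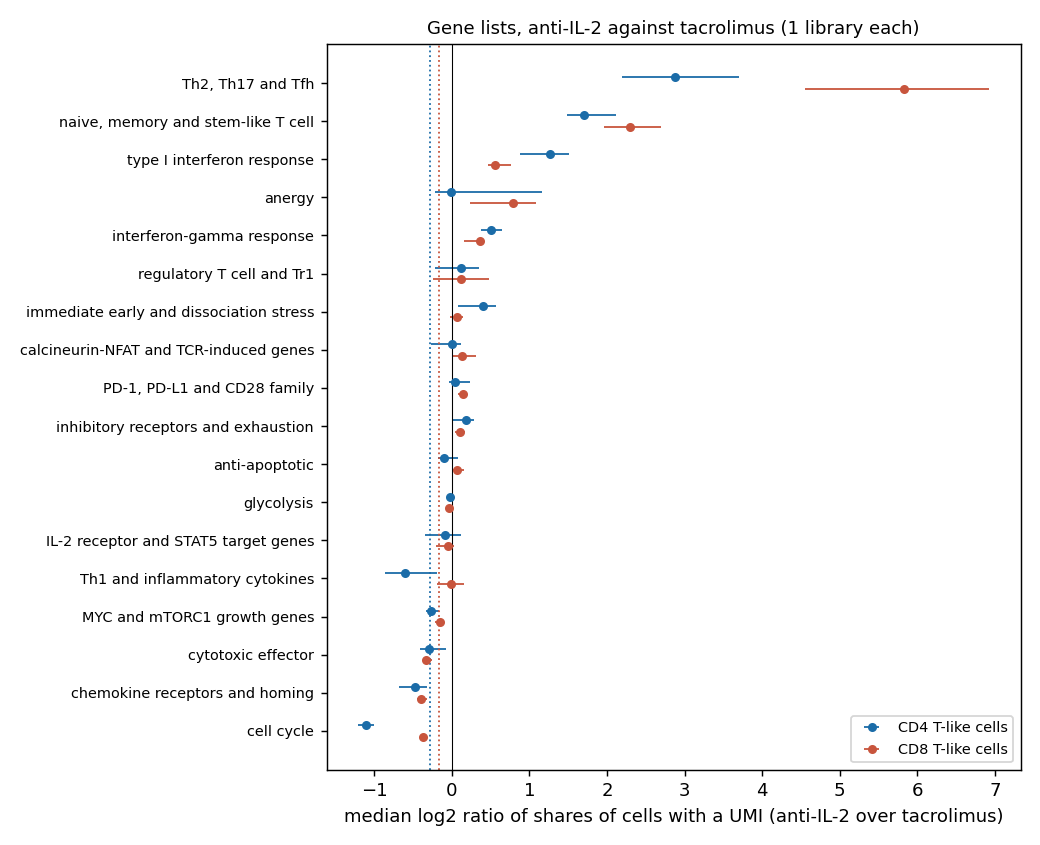
Median log2 ratio (anti-IL-2 over tacrolimus) of the share of cells with a UMI for each gene list with 3 or more measured members, in CD4 T-like cells (blue) and CD8 T-like cells (red), 1 library per treatment. Bars are 95% counting intervals and dotted lines mark the median of all genes, -0.28 in CD4 T-like and -0.16 in CD8 T-like cells; the naive list lay at 1.71 and 2.30 and the cell cycle list at -1.10 and -0.37.

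Within CD4 T-like cells, Tcf7 was detected in 73.7% of anti-IL-2 cells (68.9 to 78.1%) and 14.0% of tacrolimus cells (10.7 to 18.0%), Id3 in 48.7% and 12.4%, and Ccr7 in 28.0% and 5.39%. Of interferon genes, Ifit1 was in 27.4% against 4.85% (5.65-fold, 3.40 to 9.92), Rsad2 in 14.3% against 1.08% and Iigp1, an interferon-inducible GTPase gene, in 12.4% against 1.89%. Ccna2 was in 18.3% against 56.9% (ratio 0.321, 0.241 to 0.424) and Mki67, the Ki-67 proliferation marker gene, in 28.2% against 62.5%. Il2ra was in 12.1% (8.96 to 15.9%) against 23.5% (19.2 to 28.1%). Median depth was 9848 UMIs in anti-IL-2 and 11335 in tacrolimus cells before thinning. Most anti-IL-2 cells of the class lay in clusters 9 (43.3%) and 11 (33.3%), and most tacrolimus cells in clusters 8 (38.3%), 11 (28.3%) and 7 (22.4%). Cluster 9 was mostly of anti-IL-2 cells and may be that library, not a type.

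The lists in CD4 T-like cells gave the following counts. Of 6 naive genes 5 were in more anti-IL-2 cells (median 1.71, percentile 100), and of 15 type I interferon genes 10 were in more (median 1.27, percentile 100). Of 22 cell cycle genes 21 were in fewer and 1, Mcm6, was neither (median -1.10, percentile 0.0). Among interferon-gamma genes, Gbp5, Irgm2, Iigp1 and Socs1 were in more cells and Irf8 in fewer (median 0.50, percentile 99.7). In the IL-2 and STAT5 list, Bcl2 (57.0% against 24.0%), Socs1 and the survival kinase gene Pim2 (59.4% against 32.4%) were in more cells, and Il2ra, Socs2, Ccnd2 and Bhlhe40 in fewer. Its median of -0.09 (percentile 94.0) became 0.23 under median of ratios scaling. Ifng (15.9% against 24.3%), Ccl3 (5.11% against 13.2%), Ccl4 and Il12rb2 (19.4% against 44.5%) were in fewer cells (Th1 median -0.60, percentile 9.9). The NFAT list had a median of 0.01 (percentile 89.7), with Egr2 in more cells and Ifng, Ccl3 and Ccl4 in fewer. By mean and summed UMIs of low genes the type I interferon median was 2.88 and 3.14, the interferon-gamma median 1.93 and 1.71, and the Th1 median -1.31 and -1.09.

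Cytotoxic genes of CD4 T-like cells had a median of -0.30 (percentile 52.5), which turned to 0.02 under median of ratios scaling and 0.06 without cluster 9, and was -0.65 and -0.52 by mean and summed UMIs of low genes. Gzmc, Prf1 and Serpinb9 (40.3% against 72.0%) were in fewer cells and Lamp1 (69.6% against 44.7%) in more. Tox (61.0% against 31.8%), Tox2 and Cd200 were in more cells and Havcr2 (18.3% against 35.9%) and Entpd1 in fewer (inhibitory median 0.18, percentile 98.5, with -0.02 without cycling clusters, and -0.16 and -0.10 by those UMIs). Cxcr5 was in 29.3% against 3.77% (7.77-fold, 4.44 to 14.7). The helper subset list had 3 measured members (median 2.87, percentile 99.9, 1.87 with Ccr6 at the limit that a count of 0 allows, and 1.58 with no minimum of cells). Fos, Jun (37.1% against 21.3%), Hspa1a and Hspa1b were in more anti-IL-2 cells (immediate early median 0.41, percentile 99.8). Egr2 and Izumo1r (26.3% against 12.4%) were in more and Ndrg1 in fewer cells (anergy median 0.00, percentile 74.4), and Capg in fewer (regulatory median 0.13, percentile 95.6). Ccr2 and Itga1 were among the genes in fewer cells (homing median -0.48, percentile 19.6). Slc7a5, Nop56, Cad and Eif4ebp1 were in fewer cells, with a growth list median of -0.26 (percentile 31.1) that became 0.06 under median of ratios scaling. Other medians were 0.04 for the PD-1 family (percentile 91.9), and -0.09 for anti-apoptotic genes and -0.02 for glycolysis (percentiles 84.0 and 83.6), which became 0.22 and 0.30 under that scaling. The 12 highest genes included Rhod, Sostdc1, H2-Ob, Rsad2, Tshz2, Ifit3b, Bace2, Tox2, Slc43a1, Cxcr5 and Fam43a. Rhod was in 7.53% of anti-IL-2 cells and 0 of 371 tacrolimus cells, with a ratio whose exact 95% interval began at 7.08. The 12 lowest were 9 pancreatic genes with Gzmc, Socs2 and Msc (1.08% against 8.63%), a repressor gene of the basic helix-loop-helix family.

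Within CD8 T-like cells, Tcf7 was in 34.8% of anti-IL-2 cells (31.5 to 38.2%) and 3.90% of tacrolimus cells (2.82 to 5.26%), and Id3 in 28.6% and 3.90%. Tox was in 78.5% (75.5 to 81.3%) against 31.9% (29.1 to 34.8%), and Bcl2 in 48.6% against 17.8%. Il2ra was in 18.6% (16.0 to 21.5%) against 41.1% (38.2 to 44.2%), a ratio of 0.453 (0.374 to 0.547). The granzyme genes Gzmm (3.48% against 14.1%) and Gzmc (5.22% against 15.6%) and Klrg1 (10.2% against 21.2%) were in fewer anti-IL-2 cells. Gzmb, the main granzyme gene, was neither (91.3% against 99.1%), and in 10.0% of the 50 background cells. Its difference of -7.84 points became 0.61 with the integration shift left in. Median depth was 14132 and 14271 UMIs. Cluster 10, whose leading genes included the naive genes Ccr7 and Tcf7, held 16.4% of the anti-IL-2 and 1.6% of the tacrolimus cells of the class. Without it and cluster 9 the naive median in CD8 T-like cells was 1.5 in place of 2.30.

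Of the lists in CD8 T-like cells, the naive list had 4 of 5 members at the minimum share in more cells (median 2.30, percentile 100). The type I interferon list had 5 of 13 in more (Ifit1, Ifit3, Usp18, Oas1a, Rtp4; median 0.56, percentile 100), and the interferon-gamma list 1 of 9, Gbp5 (median 0.36, percentile 99.5). Of 22 cell cycle genes 0 passed the size rule, although the median of -0.37 lay at percentile 0.0 and Ccna2 was in 56.5% against 80%. At their tacrolimus shares, 18 of the 22 could not reach a 1.5-fold rise. Il2ra, Cish (2.98% against 6.76%), Socs2 and Ccnd2 were in fewer cells and Bcl2 in more, with an IL-2 and STAT5 median of -0.05 (percentile 85.5) that became 0.11 under median of ratios scaling. By mean and by summed UMIs, over its members in fewer than 20% of cells only, it was -1.47 and -1.52. Tox, Tox2 and Cd200 were in more cells and Havcr2 and Entpd1 in fewer (inhibitory median 0.11, percentile 99.9). Of 13 cytotoxic genes at the minimum share, 9 were in too many tacrolimus cells for a 1.5-fold rise. The cytotoxic median was -0.33 at percentile 0.1, with -0.06 without removal of the integration shift, -0.17 under median of ratios scaling, and -2.96 and -2.66 by mean and by summed UMIs of low genes. By those UMIs the type I interferon median was 1.48 and 1.67.

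Xcl1 (16.0% against 3.81%), Nr4a2 (43.4% against 25.4%) and Egr1 were the NFAT genes in more CD8 T-like cells (median 0.14, percentile 95, with 0.43 by mean and 0.00 by summed UMIs of low genes). By summed UMIs the log2 ratio of Xcl1 was 0.98, against 2.05 by shares, and that of Egr1 was 0.00. Il12rb2 was in 17.9% against 35.7% (Th1 median -0.01, percentile 86.9, with 0.15 relative to genes at the minimum share and 0.40 by mean UMIs of low genes). Ccr6 was in 11.9% against 0.10% (1 tacrolimus cell; ratio 125, 21.9 to 4997) and Cxcr5 in 10.7% against 0.10% (ratio 112, 19.6 to 4482), in a list of 3 measured members (median 5.83, percentile 99.9). That median was 0.89 with no minimum of cells and 2.44 with the tacrolimus file as deposited. Ikzf2 was in more and Maf in fewer cells (regulatory median 0.12, percentile 81.1, and -0.24 by summed UMIs of low genes), but the log2 ratio of Maf was 0.14 in anti-IL-2 cells with a readable total. Itga1 was in 5.47% against 19.5%, with a homing median of -0.40 (percentile 2.3) that became 0.03 with the integration shift left in. Slc7a5 and Eif4ebp1 were in fewer cells (growth median -0.14, percentile 26.1), and the glycolysis median was -0.04 (percentile 72.2); both turned positive, to 0.02 and 0.12, under median of ratios scaling. Other medians were 0.79 for anergy (percentile 94.0), 0.14 for the PD-1 family (98.3), 0.06 for anti-apoptotic genes (96.3) and 0.07 for immediate early genes (95.4), the last with -0.09 and -0.11 by mean and summed UMIs of low genes. The 12 highest genes included Ccr6, Sostdc1, Cxcr5, Nsg2, Dapl1, Tcf7, Tox2, Tnfrsf25, Car2, Id3 and Ociad2. Reg3b was in 0 of 805 anti-IL-2 cells, which allows up to 0.373%, and 17.1% of tacrolimus cells, and 8 other pancreatic genes stood with it, Socs2, Lmna and Olfm1 among the 12 lowest.

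**Figure D2:**
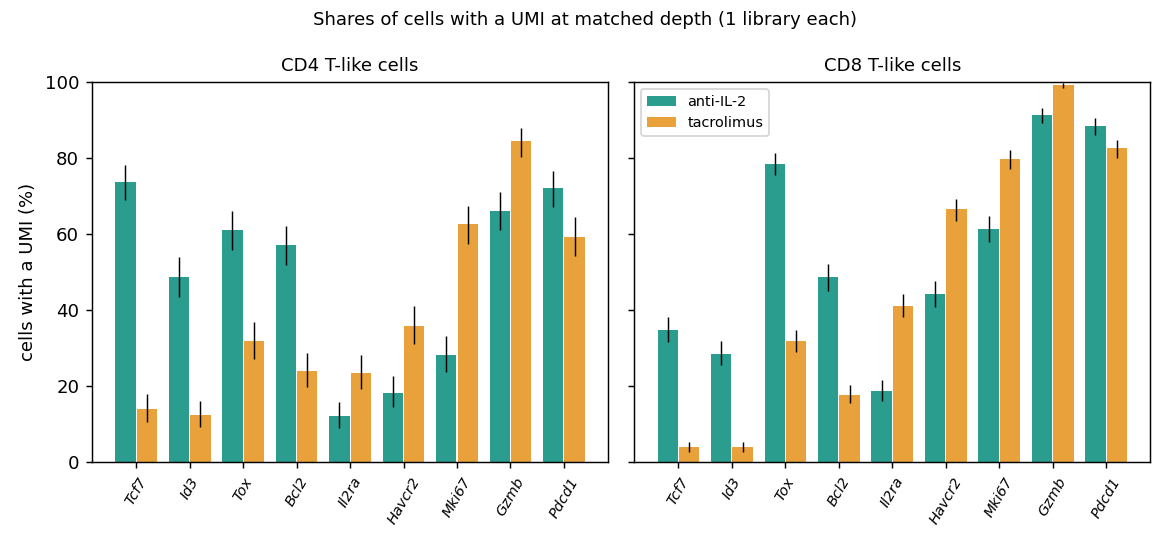
Share of cells with a UMI (%) of 9 genes in CD4 T-like and CD8 T-like cells, anti-IL-2 (green) against tacrolimus (orange) at matched depth, 1 library each, with exact 95% intervals for counting error. Tcf7 was in 73.7% against 14.0% of CD4 T-like and 34.8% against 3.90% of CD8 T-like cells, while Il2ra, Havcr2, Mki67 and Gzmb had lower shares in anti-IL-2 cells; in CD8 T-like cells the Mki67 difference turned to 4.54 points without cycling clusters and that of Gzmb to 0.61 with the integration shift left in.

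The ratios were then compared between the classes for 98 genes. Cell cycle genes were lower in anti-IL-2 CD4 T-like cells by more than in CD8 T-like cells, with a difference of log2 ratios of -1.12 (-1.5 to -0.79) for Ccna2 and -0.77 (-1.07 to -0.51) for Mki67. Iigp1 (2.09, 0.88 to 3.64) and Ifit3 (1.14, 0.18 to 2.31) had larger ratios in CD4 T-like cells. Ifng (-0.68, -1.14 to -0.22) and Ccl3 (-1.32, -2.10 to -0.61) were lower with anti-IL-2 in CD4 T-like cells, and neither in CD8 T-like cells. Cxcr5 (-2.96, -4.52 to -1.43) and Id3 (-0.89, -1.51 to -0.28) had larger ratios in CD8 T-like cells. Il2ra differed by 0.20 (-0.33 to 0.72) and Bcl2 by -0.20 (-0.56 to 0.16), differences not detectable at this depth. Hspa1b was the 1 gene that passed the size rule in opposite directions.

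The last comparison was of class shares among kept cells. CD4 T-like cells made up 29.98% of the anti-IL-2 library (27.44 to 32.61%) and 25.15% of the tacrolimus library (22.96 to 27.45%), and CD8 T-like cells 64.9% (62.1 to 67.5%) and 71.2% (68.8 to 73.5%). Without the gene minimum the CD4 T-like difference was 8.30 points in place of 4.83. The CD4 T-like shares lay closer, at 27.72% against 24.88%, with Leiden resolution 2.0. With classes from each cell's own UMIs they were 22.88% against 19.93%. Foxp3, the gene of the regulatory T-cell lineage factor, was in 1.61% of anti-IL-2 and 1.35% of tacrolimus CD4 T-like cells, below the minimum for a call.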

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

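The tests of pancreatic RNA by T-cell class, of depth, and with the pancreatic-RNA-rich cell or the clusters with Cd8b1 left out were chosen only after the results were seen, as was the test of the naive list within each class. The pancreatic gene list was written after that pattern was seen, and the rule that a ratio resting mostly on 1 cell decides nothing was set after its value of 0.04 was seen.

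Hspa1b, which encodes an inducible HSP70 chaperone, differed in direction between the classes. It was in 12.1% of anti-IL-2 and 7.01% of tacrolimus CD4 T-like cells and in 4.22% and 7.52% of CD8 T-like cells, a difference of log2 ratios of 1.57 (0.78 to 2.48, counting error only). With 1 library per treatment this difference was not tested against replicates. Hspa1b is a gene of the list of immediate early and dissociation stress.

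Cells outside the main comparison carried a signal of other lineages. They were 5.16% of anti-IL-2 (3.99 to 6.54%) and 3.66% of tacrolimus cells (2.76 to 4.75%), above the limit that a count of 0 allows. Their 4 clusters were led by endothelial, B and plasma cell, erythroid and macrophage genes. The endothelial-led cluster of 18 cells also had Cd8a in 66.7% and Cd8b1 in 83.3% of cells. Of these cells 11 were anti-IL-2, fewer than the 30 whose shift was taken as shared, so these shares are less certain.

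Pancreatic enzyme genes were in more tacrolimus T cells, in a library of spleen cells. Free pancreatic RNA in that library should reach other lineages and T cells alike, and the planned test gave a ratio of list UMIs per 10000 of 0.04 (0.04 to 0.05), outside its bound of 2-fold. That ratio, and a ratio of 0.01 for CD8 T-like over CD4 T-like cells, rested on 1 cell of the CD4 T-like class, in which 83.9% of 87844 UMIs came from the list. Without it the ratios were 1.0 (0.82 to 1.22) and 0.79 (0.73 to 0.86), which argues against expression by 1 of the T-cell classes, but the former was 0.55 (0.39 to 0.77) when only other-lineage clusters with little Cd8b1 were used, which does not decide for or against free RNA. Greater depth is argued against by a median log2 ratio of -3.98 (-4.56 to -3.71) at matched depth; free RNA and carried-over pancreatic cells or fragments stay open, and an effect of treatment was not tested.

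Naive, memory and stem-like genes were in more anti-IL-2 T cells. Another mix of classes is argued against by the lower of the class medians, 1.71 (1.46 to 2.11), fewer cycling cells by a median of 1.86 (1.5 to 1.99) without cycling clusters, and the removal of the integration shift by a median of 2.0 (1.8 to 2.24) with the shift left in. Within the classes, the median without cycling clusters was 1.06 in CD4 T-like cells, from 1.71, and 2.9 in CD8 T-like cells, from 2.30. Of 11 T clusters with enough cells of each library, cluster 9 alone had a median below 0, at -0.11 (-0.39 to 0.12). An effect of treatment is a hypothesis, and a difference between the libraries that is not due to treatment may account for the pattern as well, since there was 1 library each.

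Type I interferon genes were in more anti-IL-2 T cells. A list median of 0.3 or more was found in 8 of 11 T clusters (interval 5 to 10, added after the count was seen), which argues against a small set of cells in 1 or 2 clusters, and 10 of 11 intervals lay above 0. The stricter bound set before, more than 2 of 3 clusters, was met by the count but not by its whole interval. Fewer cycling cells are argued against by a median of 0.65 (0.51 to 0.89) without cycling clusters. Treatment and library cannot be told apart here either, and the interferon source was not tested.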

How the results depend on the processing

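Chosen only after the data were seen were the tests with other detection thresholds, the integration shift left in, readable totals, clusters 9 and 10 left out, the tacrolimus file as deposited, and summed UMIs. Across all alternatives, list medians stayed within their counting interval in 825 cases, moved beyond it in 184 and reversed in 16. Gene ratios did so in 4034, 432 and 8 cases and shares in 373, 68 and 9. Ratio intervals are too wide for genes in most cells, which makes a move beyond them less likely. The totals include alternatives that could change little. With doublets left out, or with 0.5 cells added, all 54 list medians stayed within. With cycling clusters left out 25 list medians stayed, 24 moved and 3 reversed. With only readable totals 17 stayed and 36 moved. A reversal was counted only where the main interval excluded 0. Other changes of sign, such as those of the Th1 median in all T cells, are among the cases moved or within. The naive list stayed positive in each class under every alternative run, as did the type I interferon list, and the cell cycle list stayed negative. Cells with a readable total are a selected subset. Thinning both libraries to a fixed depth underestimates anti-IL-2 shares in the simulated data. Depth limits genes in few cells, and the cause of each change below was not tested. Not run were a larger set of variable genes, since the files hold 2000, leaving ribosomal, mitochondrial and receptor genes out of the total, and a pseudocount of 0.1. Settings that use UMIs of low genes cover members in fewer than 20% of cells only. Values below are list medians in all T, CD4 T-like (CD4) and CD8 T-like (CD8) cells. Only medians that moved beyond their counting interval or reversed are listed, and other medians taken under a setting stayed within it.

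With classes from each cell's own UMIs, 1 median moved and 52 stayed within their interval, with helper subset genes at 3.96 (all T).

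With no cell filter, the medians changed, with cytotoxic genes at -0.44 (all T) and -0.43 (CD4), and naive genes at 1.82 (all T). Cell cycle genes came to -0.64 (all T), -1.32 (CD4) and -0.40 (CD8), and glycolysis genes -0.06 (all T). Homing genes stood at -0.71 (CD4) and -0.49 (CD8). The CD4 T-like share difference was 8.30 points, from 4.83.

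With cycling clusters left out, the medians changed, with inhibitory genes at 0.23 (all T), -0.02 (CD4) and 0.36 (CD8). Cytotoxic genes were at -0.44 (all T) and -0.42 (CD8), and Th1 genes -0.27 (all T). Naive genes reached 1.86 (all T), 1.06 (CD4) and 2.9 (CD8). Regulatory genes became -0.21 (all T) and 0.64 (CD8), and PD-1 family genes 0.23 (all T) and 0.36 (CD8). Cell cycle genes measured -0.43 (all T), -0.79 (CD4) and -0.18 (CD8). Glycolysis genes lay at -0.01 (all T) and 0.00 (CD8). Growth genes gave -0.05 (all T), -0.13 (CD4) and 0.05 (CD8), and immediate early genes 0.33 (all T). IL-2/STAT5 genes came to -0.40 (CD4) and 0.11 (CD8), and type I interferon genes 0.75 (CD4), and NFAT genes 0.40 (CD8). Anti-apoptotic genes stood at 0.29 (CD8). The log2 ratio of Aurkb was 0.37 (all T, from -0.76), the log2 ratio of Cdk1 was 0.05 (all T, from -0.71) and the log2 ratio of Aurkb was 1.31 (CD8, from -0.54). The log2 ratio of Ccnb1 was 0.96 (CD8, from -0.48), the share difference of Gzma was 6.08 points (CD8, from -6.85) and the share difference of Mki67 was 4.54 points (CD8, from -18.2).

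With a detection threshold of 0.65, 1 median moved and 53 stayed within their interval, with cell cycle genes at -0.59 (all T).

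With the integration shift left in, the medians changed, with cytotoxic genes at -0.17 (all T) and -0.06 (CD8), and cell cycle genes at -0.44 (all T) and -0.25 (CD8). Glycolysis genes were at -0.01 (all T) and -0.01 (CD8). Homing genes reached -0.02 (all T), -0.29 (CD4) and 0.03 (CD8). The log2 ratio of Ccr2 was 0.16 (all T, from -0.62), the log2 ratio of Ccl5 was 0.11 (CD8, from -0.21) and the log2 ratio of Ccr2 was 0.32 (CD8, from -0.56). The share difference of Gzmb was 0.61 points (CD8, from -7.84), the share difference of Gzma was 8.55 points (CD8, from -6.85) and the share difference of Il7r was 3.22 points (CD8, from -7.34).

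With only the anti-IL-2 cells with a readable total, the medians changed, with IL-2/STAT5 genes at -0.25 (all T) and -0.39 (CD4), and NFAT genes at 0.02 (all T) and -0.43 (CD4). Cytotoxic genes became -0.62 (all T), -0.49 (CD4) and -0.48 (CD8). Th1 genes measured -0.44 (all T), -1.09 (CD4) and -0.23 (CD8), and helper subset genes 4.46 (all T). Naive genes lay at 2.99 (all T) and 3.49 (CD8). Regulatory genes gave 0.61 (all T), 0.53 (CD4) and 0.68 (CD8). PD-1 family genes came to 0.23 (all T), 0.27 (CD4) and 0.19 (CD8). Cell cycle genes stood at -0.98 (all T), -1.84 (CD4) and -0.73 (CD8). Type I interferon genes were at 1.33 (all T), 1.73 (CD4) and 1.04 (CD8). Interferon-gamma genes reached 0.70 (all T), 0.72 (CD4) and 0.64 (CD8). Anti-apoptotic genes became 0.20 (all T) and 0.32 (CD8), and growth genes -0.28 (all T). Immediate early genes measured 0.54 (all T), 0.73 (CD4) and 0.21 (CD8), and glycolysis genes 0.00 (CD4). Homing genes lay at -0.27 (CD8). The share difference of Gzma was -4.49 points (CD4, from 10.7), the log2 ratio of Maf was 0.14 (CD8, from -0.71) and the share difference of Il7r was 4.95 points (CD8, from -7.34).

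With clusters 9 and 10 left out, the medians changed, with cytotoxic genes at -0.17 (all T), 0.06 (CD4) and -0.17 (CD8), and Th1 genes at 0.03 (all T). Helper subset genes gave 4.59 (all T) and 4.43 (CD8). Naive genes came to 1.84 (all T), 2.27 (CD4) and 1.5 (CD8). Cell cycle genes stood at -0.28 (all T), -0.70 (CD4) and -0.18 (CD8), and type I interferon genes 0.58 (all T). IL-2/STAT5 genes were at 0.23 (CD4), and homing genes -0.17 (CD4).

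With the tacrolimus file as deposited, the medians changed, with helper subset genes at 0.71 (all T), 1.52 (CD4) and 2.44 (CD8). Naive genes reached 1.65 (all T), 1.24 (CD4) and 1.82 (CD8). Cell cycle genes became -0.49 (all T), -0.97 (CD4) and -0.32 (CD8), and type I interferon genes 0.53 (all T).

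With median of ratios scaling, the medians changed, with IL-2/STAT5 genes at 0.08 (all T), 0.23 (CD4) and 0.11 (CD8). NFAT genes measured 0.41 (all T) and 0.32 (CD4). Inhibitory genes lay at 0.28 (all T), 0.50 (CD4) and 0.27 (CD8). Cytotoxic genes gave -0.17 (all T), 0.02 (CD4) and -0.17 (CD8), and Th1 genes 0.05 (all T). Naive genes came to 2.43 (all T), and PD-1 family genes 0.35 (all T), 0.36 (CD4) and 0.30 (CD8). Cell cycle genes stood at -0.37 (all T), -0.79 (CD4) and -0.21 (CD8). Interferon-gamma genes were at 0.58 (all T), 0.82 (CD4) and 0.52 (CD8). Anti-apoptotic genes reached 0.25 (all T), 0.22 (CD4) and 0.22 (CD8). Glycolysis genes became 0.16 (all T), 0.30 (CD4) and 0.12 (CD8). Growth genes measured -0.01 (all T), 0.06 (CD4) and 0.02 (CD8). Immediate early genes lay at 0.42 (all T), 0.72 (CD4) and 0.23 (CD8), and regulatory genes 0.44 (CD4). Type I interferon genes gave 1.59 (CD4), and homing genes -0.16 (CD4) and -0.24 (CD8).

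With mean UMIs per 10000 of low genes, the medians changed, with NFAT genes at 0.61 (all T) and 0.43 (CD8). Cytotoxic genes came to -2.59 (all T), -0.65 (CD4) and -2.96 (CD8). Th1 genes stood at 0.48 (all T), -1.31 (CD4) and 0.40 (CD8), and helper subset genes 1.81 (all T). Regulatory genes were at 0.84 (all T), and type I interferon genes 2.0 (all T), 2.88 (CD4) and 1.48 (CD8). Interferon-gamma genes reached 1.39 (all T), 1.93 (CD4) and 0.42 (CD8), and homing genes 0.01 (all T). Inhibitory genes became -0.16 (CD4), and immediate early genes 0.88 (CD4) and -0.09 (CD8), and IL-2/STAT5 genes -1.47 (CD8).

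With summed UMIs of low genes, the medians changed, with cytotoxic genes at -2.35 (all T), -0.52 (CD4) and -2.66 (CD8). Th1 genes measured 0.18 (all T) and -1.09 (CD4), and helper subset genes 1.75 (all T). Regulatory genes lay at 0.69 (all T) and -0.24 (CD8). Type I interferon genes gave 2.1 (all T), 3.14 (CD4) and 1.67 (CD8). Interferon-gamma genes came to 1.11 (all T), 1.71 (CD4) and 0.69 (CD8), and homing genes -0.14 (all T). Immediate early genes stood at -0.07 (all T) and -0.11 (CD8), and inhibitory genes -0.10 (CD4), and anergy genes -0.38 (CD4). IL-2/STAT5 genes were at -1.52 (CD8), and NFAT genes 0.00 (CD8), and naive genes 1.57 (CD8).

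With a minimum of 50 cells for members, 1 median moved and 51 stayed within their interval, with helper subset genes at 3.89 (all T).

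With no minimum of cells for members, the medians changed, with helper subset genes at 0.76 (all T), 1.58 (CD4) and 0.89 (CD8), and immediate early genes at 0.71 (CD4). Homing genes reached -0.26 (CD8).

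With Leiden resolution 2.0, 2 medians moved and 51 stayed within their interval, with type I interferon genes at 0.85 (CD4) and interferon-gamma genes at 0.35 (CD4).

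With unthinned tacrolimus cells, 1 median moved and 53 stayed within their interval, with interferon-gamma genes at 0.37 (CD4).

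With 5 cells added, 2 medians moved and 52 stayed within their interval, with helper subset genes at 1.67 (CD4) and 4.31 (CD8).

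With both libraries thinned to 6965 UMIs, the share difference of Pdcd1 was -9.94 points (CD8, from 5.97).

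With both libraries thinned to 9272 UMIs, the share difference of Pdcd1 was -11.5 points (CD8, from 5.97).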

Other observations

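The comparisons of marker genes and of clusters below were chosen only after the results were seen, and no further hypothesis was tested. Most markers of other lineages had low shares in T cells. Of erythroid genes, Hbb-bs was in 4.16% of anti-IL-2 against 0.49% of tacrolimus T cells, Hbb-bt in 1.19% against 0.07% and Hba-a1 in 0.85% against 0.21%, all below the 5% minimum for a call, which Car2 alone of the erythroid list reached. Of 4 natural killer cell genes, Fcer1g, an Fc receptor signalling chain gene, was in fewer anti-IL-2 cells (7.99% against 16.1%), and the other 3, among them Klre1 at 1.78% against 4.64%, were below that minimum. Of macrophage genes, Lyz2 was in 1.27% against 2.60% and Ms4a6c in 7.90% against 4.79%, and C1qa and C1qb were close between the libraries (1.95% and 2.55% against 2.60% and 2.18%).

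Among T clusters with at least 30 cells of each library, the interferon median was highest in cluster 11, at 1.08 (0.72 to 1.53), and lowest in cluster 9, at 0.09 (-0.04 to 0.33). Cells below the gene minimum carried the pancreatic list at 161 UMIs per 10000 in the tacrolimus library (157 to 164) and 3.44 in the anti-IL-2 library (3.1 to 3.82), but most of the former came from 3 cells, without which it was 10.1 (9.19 to 11.0). In kept anti-IL-2 cells the list was at 1.7 UMIs per 10000 in other lineages (1.45 to 1.99). It was at 0.22 in CD4 T-like and 0.24 in CD8 T-like cells, and at 1.53 in other lineages of the tacrolimus library (1.26 to 1.85). The other-lineage clusters held 11, 18, 8 and 27 anti-IL-2 cells, fewer than the 30 whose shift was taken as shared. Shifts there drew on cells outside the cluster, a case that the simulated libraries did not cover, so the value of 1.7 is uncertain. That value also includes Ctrb1, which was in 29.7% of these anti-IL-2 cells, above the share limit set for UMI ratios.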
